A study of Mus musculus with 4 samples.

How the data were processed

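Gene expression was measured in 4 mouse cell lines called induced chondrogenic cells in the labels (chondrogenic means cartilage-forming), named MK-4, MK-5, MK-7 and MK-10. Per the labels, the lines came from dermal fibroblasts of male mice aged 6 months, were grown at passage 6 in 60 mm dishes to confluence in medium with 10% serum, and gave 250 ng of total RNA each for biotin-labelled cRNA. Each line was hybridised to 1 Affymetrix array, and no untreated fibroblasts or cartilage were among the samples. Replicate numbers 1 to 4 follow the order of the lines and only name them. The labels do not say whether the lines came from separate animals or separate inductions, so the spread between lines mixes all such sources with technical noise.

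The deposited values are array signal intensities on a linear scale, made by the authors with MAS5 per the submitters' processing notes; its version and its background settings are not given in the sources used here. Tested on the values, the deposited intensity had a mean, trimmed by 2% at each end, of 500.0 on each array over 45101 probe sets. No detection calls were used here. A background was therefore taken per array as the highest signal among 27 control probe sets for Bacillus subtilis transcripts: 34.5 in MK-4, 28.6 in MK-5, 36.1 in MK-7 and 19.7 in MK-10. Spike transcripts added to a sample would raise this level, so it is a cautious one. A number of arrays this small, 1 per line, limits the precision of every value.

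Of the probe sets, 64 were controls, 34945 had 1 gene symbol, 932 had several and 9160 had none in the platform annotation. Symbols were updated through their gene identifiers in the RefSeq gene table of assembly GRCm38.p6, from which chromosome membership and gene order were also taken. Probe sets with several or no symbols were left out. A probe set was kept when it reached its array's median in at least 1 line, and the brightest probe set stood for its gene, which left 12899 genes. Signals were analysed as log2(signal + 2.36), where the pseudocount is the 10th percentile of all values; log2 differences of dim genes are understated by it. Signals of different probe sets were not set against each other.

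Each line in turn was set against the other 3 with limma 3.58.1 in R 4.3.3 (lmFit with 1 indicator, eBayes with a trend, 2 residual degrees of freedom), with Benjamini-Hochberg adjustment within the contrast and a threshold of 0.05. In this fit the lone line is assumed to vary as the other 3 do. The other lines are given as mean ± SD over 3 lines. Where all of one side lay below background, the fold is a bound: brighter signal over the background of the dim side, with geometric means over lines, written "at least N-fold". For each of 31 gene lists, the median of (line minus mean of the other 3) was placed among 10000 random lists of the same size matched on mean expression. This is a description of these arrays with no p-value. Camera in limma tested the same lists with a preset correlation of 0.01 and with an estimated one. The estimate rests on 2 residual degrees of freedom, and with it not even the list of Y-linked genes and Xist passed in MK-7. A list that does not pass with it is thus no evidence against a shift.

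The contrasts, the lists, the naming rule and most alternatives were fixed before the data were examined. Named genes were, per line, the 7 furthest above and the 7 furthest below the nearest other line, passing over symbols of predicted genes and clones; 13 cartilage, fibroblast and factor genes; and up to 4 members of each list with the largest SD. Further members are named where they passed the test. Alternatives covered the pseudocount, quantile normalization, centring on the median, the filter, the choice of probe set, the variance prior, the adjustment, a 4-fold rule with no test, and each line left out. A floor of 100 on the signal was added after seeing the data.

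The fit was tested on simulated data with the means and spread of the real genes and 200 of 12899 genes changed in 1 line, 5 times per contrast. All 4 lines were drawn with the same spread for a gene and no array effect. The simulations thus take for granted that the lone line varies as the others do, and cannot test it. In MK-4 the fit recovered 14.4% of changes of 2-fold, 69.6% of 4-fold, 83.2% of 8-fold and 87.6% of 16-fold. For 4-fold changes it recovered 28.8% in MK-5, 30.4% in MK-7 and 35.6% in MK-10, and for 16-fold changes 78.0%, 76.4% and 79.2%. With no gene changed it called at most 2 genes in any simulation. With 200 changed, unchanged genes made up 64 of 701 calls in MK-4, 48 of 457 in MK-5, 37 of 464 in MK-7 and 60 of 516 in MK-10, more than the 5% of the threshold. The list code was tested on MK-4 in 20 simulations of the 31 lists. A planted shift of 1 was placed above the central 95% of random lists in 97.9% of 620 tests. Lists with no shift lay outside it in 11.3%, more than the 5% a matched list would give, and in 6.13% once the spread was permuted among genes of like expression. Members of the lists varied more than other genes (median SD 0.40 against 0.28 on the log2 scale), which matching on mean expression does not remove, so the random lists are too narrow for them. With no shift, the lists lay outside in 14.7% of 620 tests in MK-5, 15.5% in MK-7 and 15.3% in MK-10.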

Results

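The 4 lines were each measured on 1 array, and 12899 genes passed the filter. Between 51.5% and 59.0% of probe sets lay above background on each array. The arrays differed in their distributions: the median signal was 51.9 in MK-4, 41.3 in MK-5, 39.4 in MK-7 and 33.4 in MK-10, and the highest signal was 26673 in MK-4 against 40229, 51855 and 37906. The 18S rRNA control read 9993 in MK-4 against 3002, 4194 and 6089 in MK-5, MK-7 and MK-10. The ratio of 3' to 5' control probe sets, a measure of RNA quality, was 1.13 for actin in MK-4 against 1.63, 1.84 and 1.48 in MK-5, MK-7 and MK-10, and 0.701 for Gapdh against 0.879, 0.856 and 0.916. With no control cells here, the comparisons are between the lines themselves, and the question is which genes set each line apart from the rest.

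Col2a1, Acan, Col9a1 and Col11a2 read far above background in all 4 lines, while some other cartilage matrix genes did not. Col9a2 read 37.5 in MK-4, 48.7 in MK-5, 110 in MK-7 and 105 in MK-10, and Chad and Snorc were below background in MK-4. Col2a1, the chain of type II collagen, read 12055 in MK-4, 21421 in MK-5, 28343 in MK-7 and 23529 in MK-10. Acan, the core protein of the cartilage proteoglycan aggrecan, read 6003, 15750, 15909 and 18965 in the same order. Col9a1 read 1440, 9748, 14931 and 11498, and Col11a2 1521, 3984, 6672 and 9768. Sox6, a transcription factor of chondrocytes, read 802, 2238, 1966 and 3038, Sox5 210, 34.4, 50.5 and 66.7, and Sox9 256, 393, 145 and 339. Col1a1, a chain of the type I collagen of skin and bone, read 1931 in MK-4 and was below background in the other 3 lines. Col1a2 read 92.5, 50.8, 60.0 and 43.3, above background in each line. Its other probe sets did not pass the filter and were below background in every line, the highest reading 24.9 in MK-7. Col10a1, made by hypertrophic chondrocytes, read 816, 1265, 170 and 1327. Myc read 911, 638, 818 and 845, and Klf4 2497, 887, 964 and 1481. No probe set with Runx2 as its 1 symbol was analysed here.

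**Figure D1:**
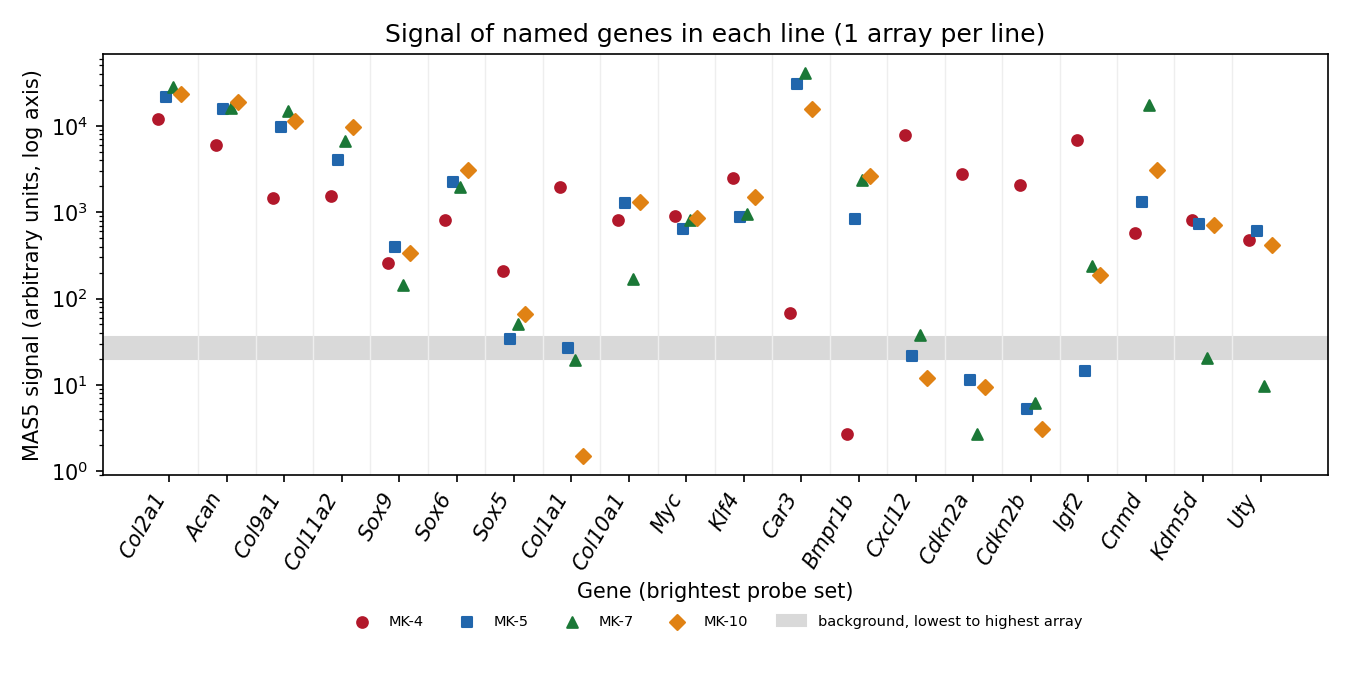
Signal of 20 named genes (log axis, arbitrary MAS5 units) in MK-4, MK-5, MK-7 and MK-10, 1 point per line, with the background range of 19.7 to 36.1 in grey. MK-4 lay below the other lines for Col2a1, Acan, Car3 and Bmpr1b and above them for Cdkn2a, Cdkn2b and Cxcl12, and MK-7 alone was at background for Kdm5d and Uty.

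Across genes, which are not independent replicates, MK-4 was the least like the rest. Pearson's r between its log2 signals and those of MK-5, MK-7 and MK-10 was 0.900, 0.883 and 0.886, against 0.951 for MK-5 with MK-7, 0.961 for MK-5 with MK-10 and 0.961 for MK-7 with MK-10. Genes over 4-fold apart numbered 939, 1114 and 1179 for the pairs with MK-4 and 532, 444 and 428 for the others. With the brighter signal of the pair at 100 or more they numbered 649, 762 and 857 against 181, 128 and 80, so most of the differences among MK-5, MK-7 and MK-10 were in dim genes. Where a gene had more than 1 probe set (5973 genes), the deviations of its 2 brightest probe sets correlated at r = 0.722 in MK-4, 0.498 in MK-5, 0.491 in MK-7 and 0.567 in MK-10; randomly paired genes gave values between -0.01 and 0.01.

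Among the genes furthest from the nearest other line in MK-4 were a pair of cell cycle inhibitors and a chemokine on the higher side, and an enzyme and a receptor on the lower side. Cdkn2a and Cdkn2b, neighbouring genes for inhibitors of the cell cycle, read 2761 and 2069 in MK-4 and were below background in the other 3 lines, at least 101-fold and at least 75.9-fold apart (adjusted p = 0.0112 and 0.0106, limma with Benjamini-Hochberg adjustment). Cxcl12, a chemokine of stromal cells, read 7911 against 23.7 ± 13.1 (SD, n = 3; adjusted p = 0.0073 by limma); of its 2 other probe sets, 1 was dim and read 39.2 in MK-4 against 45.3 in MK-7. Car3, carbonic anhydrase 3, read 68.7 in MK-4 against 28994 ± 12557 (adjusted p = 0.00676 by limma), and Bmpr1b, a receptor for bone morphogenetic proteins, was below background against 1936 ± 964, at least 49.9-fold lower (adjusted p = 0.00725 by limma).

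Of the 12899 genes tested by limma with Benjamini-Hochberg adjustment, 387 were called in MK-4, 199 higher and 188 lower, and 2706 had an unadjusted p under 0.05; these counts include any effect of its single culture or array. The other genes named for the size of their gap to the nearest line all passed. Krtdap, a keratinocyte gene, was at least 379-fold higher, Upk3b at least 156-fold, the epithelial and mesothelial transcription factor Bnc1 at least 102-fold and Nexmif at least 23.5-fold. Adamtsl2 was at least 76.5-fold lower, Chrdl2, a secreted inhibitor of bone morphogenetic proteins, at least 55.6-fold, Foxd3 at least 13.2-fold and Isl1 at least 11.7-fold. Smoc2 read 51.2 against 5100 ± 3231. The count depended on the model: 69 genes passed when adjusted over the 4 contrasts together and 74 with no trend in the variance prior. Without MK-5 it was 721 and without MK-7 116.

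The 23 cartilage matrix genes had a median of -1.50 on the log2 scale in MK-4, below each of the 10000 random lists. Of them 9 fell and 1 rose in the limma test over all genes, against 14 and 3 when adjusted over the list alone. Matn1, a matrilin of the cartilage matrix, read 97.1 against 6273 ± 2139, Col9a3 209 against 4911 ± 1382, Ucma 188 against 5417 ± 2475, and the differences of Col9a1 (-3.04 ± 0.27, SE) and Acan (-1.49 ± 0.21) also passed. Matn4 went the other way, at 6914 against 428 ± 89.2. Col2a1 (-1.01 ± 0.23; adjusted p = 0.0729 by limma) and Col11a2 (-2.07 ± 0.46; adjusted p = 0.0706) did not pass. The brightest decile of all genes had a median of -0.25 in MK-4, so bright genes read low on that array in general, and the 18S control and the actin and Gapdh ratios of MK-4 lay outside the range of the other arrays too. Among 17 chondrogenic regulators (median -0.87) Bmpr1b, Trps1 and Sox6 fell and none rose, against 7 and 1 when adjusted over the list alone. Sox9 did not differ beyond its error (-0.07 ± 0.58), and its sign turned with its second probe set (0.28). For Trps1, 1 of 3 other probe sets gave 0.11. Both lists passed camera with its preset correlation (adjusted p = 1.21e-05 and 0.00221) and neither did with an estimated correlation (adjusted p = 0.77 with an estimated correlation for both).

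Several groups of other functions were shifted upward in MK-4, the array whose 18S control was highest and whose actin and Gapdh ratios were lowest. Among 15 p53 targets and cell cycle inhibitors the median was 1.74, and 6 rose (11 when adjusted over the list alone): Cdkn2a, Cdkn2b, Mdm2, Phlda3, Zmat3 and Aen. Mdm2, which encodes the main negative regulator of p53, read 2852 against 749 ± 200, and Phlda3 read 9786 against 2697 ± 436. Of the 15 genes 14 had positive differences. Cdkn1a of this list read 11253 in MK-4, close to MK-10 (11225), against 6824 in MK-5 and 8519 in MK-7. Cdkn1b read lowest in MK-4 (1286). The 19 proliferation genes all had positive differences, with a median of 1.08, although none was called either over all genes or when adjusted over the list alone. Mki67 read 2849 in MK-4 against 1570, 1878 and 917, and Top2a 3294 against 1992, 2096 and 897. The 20 dermal fibroblast genes had a median of 1.46, and 4 rose (8 higher and 2 lower when adjusted over the list alone): Col1a1, Postn, Pi16 and Crabp1. Of 13 inflammatory genes 3 rose, Cxcl12, Ccl2 and Il6 (median 1.98; 5 when adjusted over the list alone), and of 9 epithelial genes 2, Perp and Dsp (median 2.42; 4 when adjusted over the list alone). The median was 1.30 for 14 interferon response genes, of which Bst2 rose (2 when adjusted over the list alone). The epithelial list was split: 9 of its 15 genes were measured, 6 with positive and 3 with negative differences. Krt19 and Cdh1 were above background in MK-4 alone, so they passed the filter through that line. Col1a1, Pi16, Crabp1, Cxcl12, Il6, Cdkn2a and Cdkn2b likewise reached their array's median in MK-4 alone. Genes that passed the filter in this way could only read higher in MK-4. They therefore raise the medians and the numbers of risen genes of their lists. With an estimated correlation camera passed none of the lists named here, and the medians stand as descriptions of 1 array.

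MK-5 had no gene past the threshold in limma, with 196 genes at an unadjusted p under 0.05. With no differences, 645 of the 12899 genes would be expected at such a p. MK-4, the line least like the rest, is part of the spread used as error here. The absence of calls is therefore no evidence that MK-5 is like the other lines. Cavin4, Igfbp2 and Ctla2a lay furthest above the nearest other line and Igf2 furthest below it. Cavin4 read 113 and was below background in the other lines, at least 3.90-fold apart. Ctla2a, a cysteine protease inhibitor, read 1745 in MK-5 against 119 ± 37.4 (SD, n = 3), and Igfbp2, which binds insulin-like growth factors, 663 against 30.0 ± 22.1. Igf2 was below background in MK-5 and read 6775 in MK-4, 239 in MK-7 and 188 in MK-10. Ctla2b read 380 against 39.1 ± 21.6 and Lyz1 623 against 44.2 ± 40.6. Clec3b was below background in MK-5 against 335 ± 264 in the other lines, at least 8.75-fold lower, and Pcsk5 and Igfals were at least 3.54-fold and 2.06-fold lower. Vwa7 at 45.9 and Trgv4 at 45.8 were near background. Pdilt, Sfrp2 and Spink2 were below background in MK-5. Each of these had an adjusted p of 0.9998 (limma with Benjamini-Hochberg adjustment).

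The array of MK-5 had the lowest 18S control (3002). On it 8 housekeeping genes had a median of 0.29, also outside the central 95% of random lists, beside which its other shifts stand. Of 13 cholesterol synthesis genes 12 had negative differences in MK-5, with a median of -0.42 below each of the 10000 random lists and 0 called over all genes or when adjusted over the list alone. Hmgcs1 read 3790 in MK-5 against 5105, 6622 and 6670 in MK-4, MK-7 and MK-10, and Insig1 2062 against 1990, 3886 and 3739. The median of 13 genes of unfolded protein and amino acid stress was 0.42, with 12 positive and none called. Camera passed both lists with the preset correlation (adjusted p = 1.96e-05 and 0.0106) and neither otherwise (adjusted p = 0.77 with an estimated correlation).

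MK-7, which per the labels came from male mice like the other lines, lacked signal of the measured Y-linked genes. The cause was not tested. Kdm5d read 20.7 in MK-7 against 752 ± 45.5 (SD, n = 3), Uty 9.59 against 501 ± 99.3 and Eif2s3y 12.1 against 1412 ± 841, so that these were at least 20.8-fold, 13.7-fold and 33.4-fold lower, all below background. Xist, the transcript of the inactive X chromosome, read 31.9, 38.3, 52.9 and 18.4 in MK-4, MK-5, MK-7 and MK-10. The adjusted p was 0.302 for Kdm5d and 0.383 for Uty within the contrast (limma with Benjamini-Hochberg adjustment), and the 3 Y-linked genes passed when adjusted over the list alone. Adjusted over the 4 contrasts together, Kdm5d and Uty were the only genes of MK-7 to pass, with log2 differences of -5.03 and -5.38. That adjustment pools the many small p-values of MK-4 with those of MK-7, which eases the threshold for MK-7. It adds no evidence about MK-7 itself.

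Within its own contrast MK-7 had 0 genes past the threshold in limma, with 294 at an unadjusted p under 0.05. Here too 645 would be expected at such a p with no differences, and MK-4 is part of the spread used as error. Cnmd, which encodes the cartilage glycoprotein chondromodulin, read 17271 in MK-7 against 574 in MK-4, 1316 in MK-5 and 3046 in MK-10. Htra4, a serine protease gene, read 805 against 36.0 ± 13.3. Thbs1, the matrix protein thrombospondin 1, read 167 against 8487 ± 7165, and Ptgs2, Ang2 and Lyz1 were below background, at least 3.05-fold, 4.52-fold and 3.77-fold lower. A second probe set of Ptgs2 read 17.6 in MK-7 and 12.9 in MK-4, both below background. Ndufa4l2 at 126 and Fbp2 at 153 were at least 4.69-fold and 5.70-fold higher, and Slc22a14, Gh and Rbakdn lay between 49.4 and 57.8, near background. The array of MK-7 had the highest actin ratio (1.84), the highest maximum signal (51855) and the lowest share of probe sets above background (51.5%), beside which its list shifts stand. The 8 adipocyte genes had a median of 1.50 in MK-7 and 0 called (1 higher when adjusted over the list alone): Fabp4 read 520 against 223, 130 and 38.3 in MK-4, MK-5 and MK-10, and Cebpa 734 against 340, 150 and 286. All 13 inflammatory genes had negative differences (median -1.79), and 13 of 14 genes of hypoxia and glycolysis positive ones (median 0.54), with none called. All 13 inflammatory genes were positive in MK-4 (median 1.98), which is part of the mean that MK-7 was set against. Cxcl12, near background in MK-7 (37.8), still read lower in MK-5 (21.4) and MK-10 (11.9). The 12 ribosomal protein genes had a median of 0.55 in MK-7 and -0.58 in MK-4, while the brightest decile of all genes had 0.22 and -0.25. With an estimated correlation none of these lists passed camera (adjusted p = 0.77 with an estimated correlation).

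In MK-10 the 19 proliferation genes were all below the mean of the other lines, on the array with the lowest median signal (33.4) and the highest Gapdh ratio (0.916). Their median was -1.25, below each of the 10000 random lists; 0 were called over all genes and 6 fell when adjusted over the list alone. Aurkb read 165 in MK-10 against 694, 372 and 482 in MK-4, MK-5 and MK-7, Birc5 599 against 2774, 1177 and 1713, and Aurka 168 against 903, 417 and 442. The list passed camera with the preset correlation (adjusted p = 2.87e-18) and not otherwise (adjusted p = 0.77 with an estimated correlation). The 20 dermal fibroblast genes had a median of -0.85 with none called, over all genes or when adjusted over the list alone.

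MK-10 had 0 genes past the threshold in limma, with 282 at an unadjusted p under 0.05. As for MK-5 and MK-7, 645 would be expected at such a p with no differences, and MK-4 is part of the spread used as error. Chad, which encodes the cartilage matrix protein chondroadherin, read 1822 in MK-10 against 201 in MK-5 and 389 in MK-7 and was below background in MK-4. Hrc read 756 against 93.2 ± 69.3. Epyc, a small proteoglycan of cartilage, read 27.4 in MK-10 against 352 ± 76.9, and Mmp14, a membrane-bound matrix protease, was below background against 4411, 74.3 and 64.7 in MK-4, MK-5 and MK-7. The gap of Mmp14 to MK-5 rests on this probe set, as both its other probe sets were below background in MK-5 and MK-10, and 1 of them read higher in MK-10 (13.7) than in MK-5 (5.16) and MK-7 (4.40). Chil1 was at least 4.31-fold and Olfml1 at least 3.35-fold lower. Dlx6, Dlx6os1, Bcl2l14, Hlx and Eda read 73.8, 95, 93.6, 44.9 and 45.7 in MK-10, and Orm2, Fat4 and Cspg5 were below background there. The adjusted p of each was 0.9998 (limma with Benjamini-Hochberg adjustment).

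**Figure D2:**
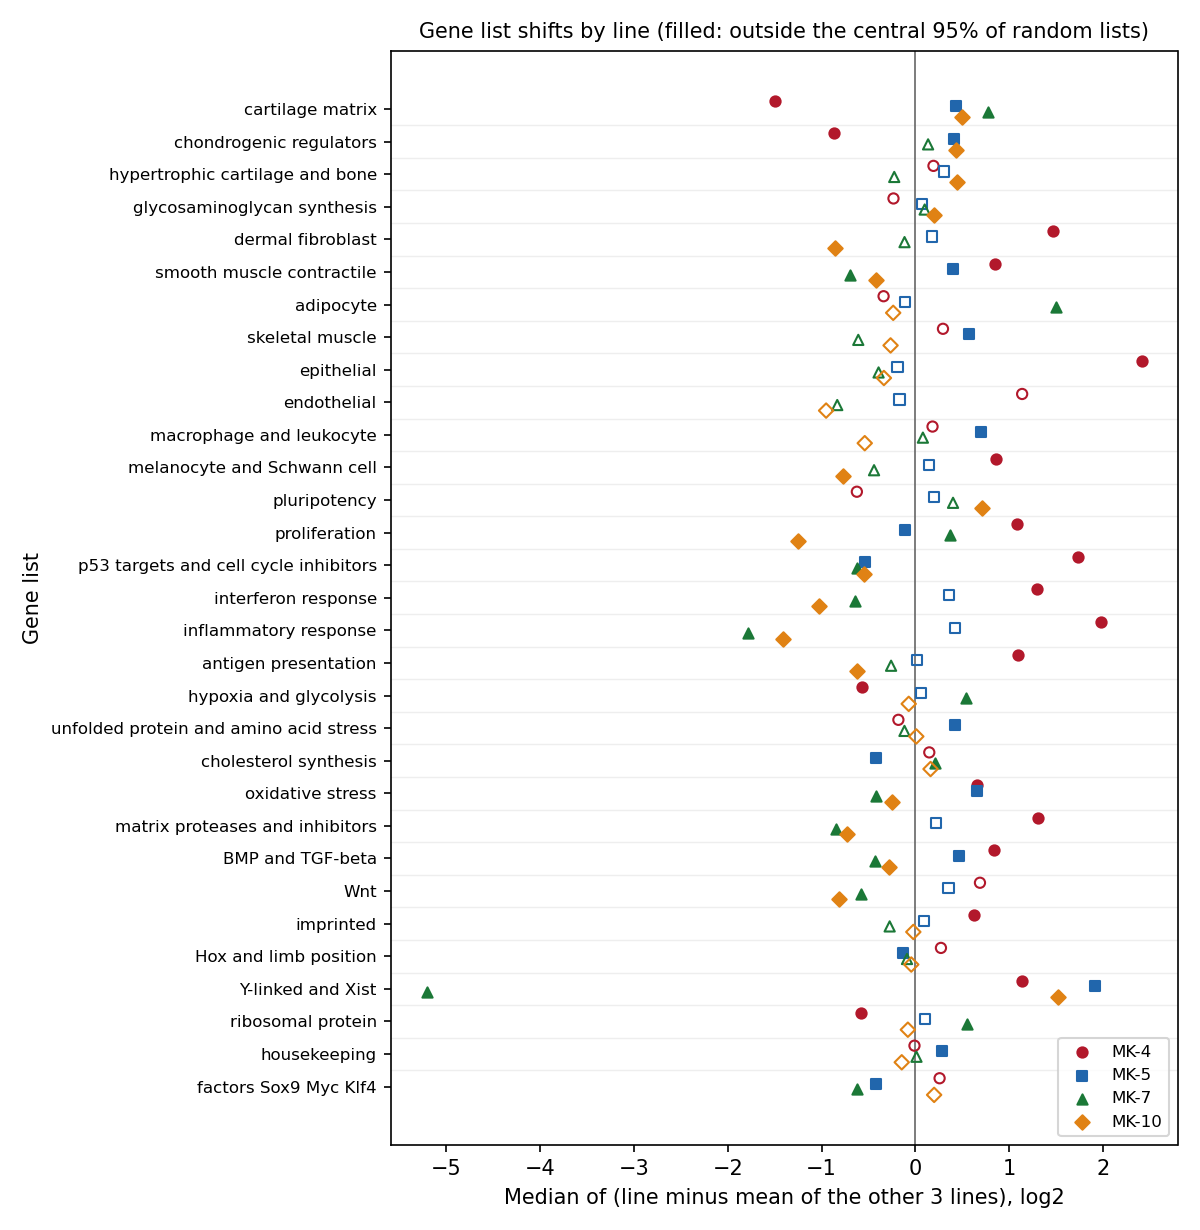
Median of (line minus mean of the other 3 lines) on the log2 scale for 31 gene lists in MK-4, MK-5, MK-7 and MK-10; filled points lie outside the central 95% of 10000 matched random lists. The Y-linked list in MK-7 (-5.21) and the epithelial list in MK-4 (2.42, 6 of 9 genes positive and 3 negative) lie furthest out. The cartilage matrix list lies below 0 in MK-4 (-1.50), turning sign in MK-5 and MK-10 when MK-4 was left out.

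Of the 124 medians, 67 lay outside the central 95% of random lists where 17.6 would by chance at the rate of unshifted lists in simulations of the 4 contrasts, and more where genes move together. Camera called 27 of the 124 with the preset correlation and 0 with an estimated correlation. Each line's difference is taken against the mean of the others, so a line far from the rest moves all 4 contrasts. The cartilage matrix medians of 0.43 in MK-5 and 0.50 in MK-10 became -0.14 and -0.045 without MK-4, and those of the p53 list, -0.53 and -0.54, became 0.16 and 0.075.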

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

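The tests of a mixture of cells, of dependence on expression level, of the Mtap gene and of the Cdkn2 genes themselves were chosen after the result was seen. The tests of scaling and of a lone array were set out before their result was seen. A line was looked at again when its gap to the nearest other line, divided by the range over the 4 lines, was above the 95% critical value for 4 samples. Chance gives this in about 1 of 20 groups, so 5.3 of the 106 measures tested; 26 met it. Of these 20 were single genes, most of them named for the size of this same gap, which makes their number no evidence by itself. Over all 12899 genes, 476 met the rule in MK-4, 97 in MK-5, 138 in MK-7 and 88 in MK-10. Chance would give 645 over the 4 lines together.

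MK-4 stood apart for 3 gene lists and 9 genes. Its share of the range was 0.850 for the cartilage matrix list, 0.928 for the epithelial list and 0.962 for the p53 targets and cell cycle inhibitors. For single genes it was 0.857 for Bnc1, 0.831 for Upk3b, 0.925 for Cdkn2b, 0.843 for Cdkn2a, 0.836 for Cxcl12, 0.945 for Nexmif, 0.850 for Car3, 0.939 for Foxd3 and 0.839 for Acan. MK-7 stood apart for the adipocyte list at 0.875, the list of Y-linked genes and Xist at 0.891, Ndufa4l2 at 0.856, Slc22a14 at 0.988, Gh at 0.930, Uty at 0.902 and Kdm5d at 0.968. MK-5 did so for the cholesterol synthesis list at 0.896, Cavin4 at 0.882, Vwa7 at 0.909, Trgv4 at 0.866 and Pdilt at 0.864, and MK-10 for Bcl2l14 at 0.880 and Epyc at 0.839. No array measure among the 8 tested did so.

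The first pattern is the distance of MK-4 from the other 3 lines. Scaling between arrays and compression of bright signals are argued against as its whole cause, since 97.2% of its 387 called genes were called again under quantile normalization. A mixture of cells like the other lines with another cell type would leave each gene of those cells at about 1 share of its level; Acan and Col2a1 kept 38.1% and 56.3% of the lowest other line, while 16 of the 188 genes called lower, Car3 and Bmpr1b among them, were below 5% of it, 10 of these where that 5% clears the background. This argues against such a mixture only if those cells kept the levels of the other lines and the other cells made no Acan or Col2a1. Neither was tested, and the genes below 5% were taken from those already called lower. A mixture with cells of another profile is left open. MK-4 has 1 array, so a difference of the line cannot be told apart from one of the culture or the hybridisation. No other biological explanation was tested.

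The second pattern is that Cdkn2a and Cdkn2b were below background in MK-5, MK-7 and MK-10, as all 6 values of the pair were. Complete loss of a longer segment that reaches their neighbour Mtap (in gene order on assembly GRCm38.p6) is argued against: all signals of 4 Mtap probe sets were above background. The lowest ratio of any of these lines to MK-4 was 0.638, which does not exclude a loss that leaves a copy of Mtap. Dmrta1, in the same region, read 211, 270 and 282 in MK-5, MK-7 and MK-10 against 52.3 in MK-4. No untreated cells were measured, so the values cannot tell a fall in MK-5, MK-7 and MK-10 from a rise in MK-4. Krtdap, Upk3b, Bnc1 and Nexmif were also high in MK-4 and below background in the other lines. If the pair fell, deletion or silencing of the Cdkn2a and Cdkn2b genes themselves may underlie the pattern. Deletion and silencing cannot be told apart by the 6 values, since transcripts alone were measured.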

How the results depend on the processing

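The floor of 100 on the signal was chosen after seeing the data; all other settings were planned. The count of 387 genes in MK-4 was 257 with no filter, 780 with the floor of 100 (669 higher and 111 lower), 74 without the trend (59 higher and 15 lower) and 69 when adjusted over the 4 contrasts together, and it ranged from 116 to 721 when each other line was left out. Under quantile normalization 212 were higher and 279 lower, with a median over all genes of -0.11 in MK-4. With no test, 67, 86 and 89 genes were over 4-fold from each other line in MK-5, MK-7 and MK-10, where limma called 0 (28 higher and 39 lower, 27 and 59, and 9 and 80); with signal plus pseudocount at 100 or more, in the line if higher and in each other line if lower, they were 20 and 3, 11 and 11, and 2 and 10. The dimmest decile of genes had a median of -0.57 in MK-10. MK-7 had 2 called when adjusted over the 4 contrasts. Without MK-4 these 3 lines still had 0 called, with 932, 713 and 439 genes at an unadjusted p under 0.05. The mean r of MK-4 with the others, 0.889, was 0.902 with the pseudocount at the 25th percentile, 0.935 with no filter, 0.869 with the filter on the mean, 0.868 with the mean of all probe sets, 0.899 with the floor and 0.916 by Spearman. Of the 124 list medians, 67 lay outside random lists, while camera called 27 of the 124 with the preset and 0 with the estimated correlation. Single list medians turned sign as follows: macrophage genes in MK-5 with no filter (-0.32), matrix proteases in MK-4 with the filter on the mean (-0.095) and with the floor (-0.095), housekeeping genes in MK-5 with the mean of probe sets (-0.019) and smooth muscle genes in MK-4 with the floor (-0.031). With each other line left out in turn, the medians ranged from -0.14 (without MK-4) to 0.56 for cartilage matrix in MK-5, -0.045 (without MK-4) to 0.96 for it in MK-10, -0.13 (without MK-7) to 0.91 for hypertrophic cartilage in MK-10, -0.63 to 0.21 (without MK-4) for proliferation in MK-5, -0.084 (without MK-10) to 0.74 for it in MK-7, -0.70 to 0.16 (without MK-4) for the p53 list in MK-5, -1.01 to 0.075 (without MK-4) for it in MK-10, -0.40 to 0.14 (without MK-4) for BMP and TGF-beta in MK-10, and -0.24 (without MK-7) to 2.43 for the Y-linked list in MK-10. Likewise Sox9 in MK-4 ranged from -0.51 to 0.20 and Col10a1 from -0.67 to 0.81. Sox9 in MK-4 turned with the mean of probe sets (0.11) and another probe set (0.28), and Trps1 with another probe set (0.11). The cause was not tested. Of 1633 settings of single genes, 213 lost the threshold, 4 gained it and 6 turned sign. Only the genes called in MK-4 could lose it, so the share lost among them is higher than these totals give. Dim signals limit the folds: of the 14 genes named by their gap in each line, 11 in MK-4, 10 in MK-5, 11 in MK-7 and 11 in MK-10 had a whole side below background.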

Other observations

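Expression by chromosome was looked at after the data were seen, and the test against expression level was chosen then too.

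Some biology lies outside the groups above. Of 8 genes of melanocytes and Schwann cells, Erbb3 rose in MK-4 in limma (4163 against 1120 ± 232, SD, n = 3; 3 higher and 1 lower when adjusted over the list alone). Of 6 pluripotency genes, Sox2 fell (336 against 1688 ± 528; 1 lower when adjusted over the list alone). Hoxd13, a homeobox gene of the distal limb, rose in MK-4 (631 against 29.0 ± 18.3), and Hoxa7 fell (47.1 against 244 ± 37.4), the only called members of the 35 Hox and limb position genes. Of the Wnt list Sfrp2, Lef1 and Fzd1 rose in MK-4 and Frzb fell. Mgst1, a glutathione transferase gene, rose (7961 against 347 ± 83.1), and Papss2, which makes the sulfate donor for proteoglycans, fell (3155 against 18552 ± 4226). The imprinted gene Dlk1 rose in MK-4 (616 against 46.0 ± 15.8).

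The median over a chromosome differed by a little from the rest in some lines. Over 8036 genes with a mean signal above 300, taken relative to each line's own median, the median was 0.24 for chromosome 1 and 0.19 for chromosome 15 in MK-4, and for chromosome 4 it was -0.25 in MK-4, 0.20 in MK-7 and 0.18 in MK-10; no other of the 80 medians passed 0.11 in size. A change in copy number is a candidate explanation that no value here tests, as no DNA was measured. Of the 80 medians 8 lay outside all 10000 random sets matched on mean expression (10 with a limit of 200 on the mean signal): these 5, and the smaller ones of chromosome 1 in MK-7 (-0.11) and MK-10 (-0.068) and of chromosome 4 in MK-5 (-0.082). The 5 were picked for their size, so that all 5 did so is no evidence by itself. The highest matched median was 0.14 for chromosome 1 and 0.11 for chromosome 15 in MK-4. For chromosome 4 it was 0.076 in MK-7 and 0.066 in MK-10, and the lowest in MK-4 was -0.10. Expression level alone thus gave no medians of the size seen, although neighbouring genes are not independent as such sets assume. With each chromosome split into 4 equal segments in gene order, the segment medians of chromosome 4 were -0.38, -0.47, -0.18 and -0.032 in MK-4, 0.26, 0.29, 0.17 and -0.044 in MK-7, and 0.28, 0.26, 0.14 and 0.032 in MK-10, so the last segment lay near 0 in these 3 lines. Those of chromosome 1 in MK-4 lay between 0.16 and 0.33 and those of chromosome 15 between 0.13 and 0.27. Without MK-4 the chromosome 4 medians were -0.18 in MK-5, 0.09 in MK-7 and 0.10 in MK-10, and with a limit of 200 on the mean signal the same number of medians, 5, passed 0.15.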
